A study of Mus musculus with 12 samples.

How the data were processed

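RNA-seq of whole liver was analysed in 12 libraries, 3 from sham-operated mice and 3 each from mice at 3, 6 and 12 h after a 70% partial hepatectomy. Per the labels, the mice were wild-type C57/BL6J, RNA was extracted with TRIzol, and poly(A) libraries were made with a NEBNext Ultra kit. The tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with GRCm38 (mm10), per the submitters' processing notes, in which the role and order of each are not stated. The deposited table held 54532 genes, with a count and an FPKM value per library under its column headers and a gene length. The deposited counts were whole numbers with no normalization. From the values, the deposited FPKM were the counts divided by gene length and by an effective library size, equal to the geometric mean of the library totals times a median-ratio size factor. Gene identifiers and positions were as deposited, and 54495 of them are in GENCODE M21, 53585 with the same start and end. The strand used in counting is not stated, so reads of overlapping genes may not be separable. Samples were grouped by their titles, including 6 h replicate 3, whose time tag says 7 h.

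The test planned was limma on log2(FPKM + 1), because FPKM alone were expected. Since the table held counts, the main test became the edgeR quasi-likelihood test on the counts with TMM scaling, and the limma fit was kept as an alternative. Genes with 1 FPKM or more in 3 or more of the 12 libraries were tested, 11451 in all, and these held 99.1% or more of the counts of each library. One model with the 4 groups was fitted to all 12 libraries, and each contrast was tested on both sides with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. Group values were counted as not overlapping where all 3 libraries of a group lay above all 3 of the other, which happens by chance for 10% of genes. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1, data.table (version 1.17.8) and DESeq2 1.42.0.

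Of 45 fixed lists of pathway and cell type genes, 43 had 3 or more tested genes and were tested with limma camera at a preset correlation of 0.01 on edgeR log CPM with a prior count of 2. Adjustment was over the lists of a contrast, and the test was repeated with the correlation estimated per list and with fry. Members called are given after adjustment over all genes and after adjustment over the list alone. Of 1097 list symbols, 2 had no match in the table. Genes are named by 3 parts of a rule. Part (a) takes the 5 largest rises and the 5 largest falls per comparison with sham, and 3 and 3 between successive times, among called protein-coding genes with named symbols, a mean of 5 FPKM or more in the higher group and no overlap between the groups. Part (b) allows up to 4 called members of each list as examples, those with the largest differences, or up to 2 where no member was called. Part (c) takes 15 genes fixed in advance. Some genes that the rule takes are not reported here. Genes with 10 or fewer counts in a group are given as a ratio of counts with a 95% Clopper-Pearson interval, which covers counting error only.

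Library totals of 15573405 to 17199639 counts and a biological coefficient of variation of 20.6% set the precision. In data simulated for 3 h against sham, 8 of 11251 unchanged genes were called and 50 of 50 changed 8-fold. In data simulated for 6 h against sham, a list of 45 genes raised 2-fold was called and none of 42 unchanged lists. Correlation between the genes of a list was not simulated. The results were recomputed with a pseudocount of 0.1, no filter, TPM, median-ratio scaling, quantile normalization, only the 6 libraries compared, the replicate number as a block, robust estimation, voom, a 2-fold minimum and each library left out in turn. After the data were seen, limma on FPKM, DESeq2, scaling by library totals, scaling without mitochondrially encoded and acute phase genes, a fit without both doubted libraries (sham replicate 1 and 6 h replicate 3), and list tests between 12 h and 3 h were added. The values with a pseudocount of 0.1, TPM and quantile normalization were fitted with limma on the log2 scale. No library was left out of the main test, and genes under the filter were left out because their values rest on few reads.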

Results

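Poly(A) RNA from whole liver of wild-type C57/BL6J mice was sequenced in 12 libraries, 3 from sham-operated livers and 3 each from livers taken 3, 6 and 12 h after resection. The operation was a 70% partial hepatectomy, after which the remaining lobes grow until the original liver mass is restored. The comparisons ask how expression changes in the hours that prepare the liver for growth. The labels give no hour for the sham livers, and 6 h replicate 3 carries a time tag of 7 h beside a title of 6 h and was grouped by its title. The labels do not say outright that the libraries of a group came from separate animals, so the p-values may measure only the spread between these samples. Library totals lay between 15573405 and 17199639 counts, and 11451 genes were tested. Levels are given as FPKM (mean ± SD, n = 3 libraries per group), differences on the log2 scale as fitted by edgeR, and positions on GRCm38.

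The first principal component, with 38.2% of the variance, set the 3 h and 6 h livers apart from sham and 12 h livers, and the second, with 27.0%, followed time after resection. Acute phase transcripts took up 2.43% to 2.88% of the counts in sham livers, 7.60% to 8.65% at 3 h, 13.3% to 14.9% at 6 h and 10.7% to 12.0% at 12 h. Sham replicate 1 stood apart from the other sham libraries, with correlations across genes down to 0.950 against 0.978 or more within the groups at 3, 6 and 12 h. Mitochondrially encoded transcripts made up 11.9% of its counts, against 6.26% and 5.52% in sham replicates 2 and 3. Its levels also differed for genes named below, such as Cyp7a1 (39.6 FPKM against 9.61 and 13.6), Dbp (2.08 against 10.2 and 7.11) and Jun (1.18 against 9.93 and 7.17). Across the 4 groups, 5725 of 11451 genes differed by the edgeR F-test. Of 43 gene lists fixed before the data were examined, 20, 17 and 16 were called against sham at 3, 6 and 12 h by camera with a preset correlation. With an estimated correlation camera called 1, 1 and 2. Other splits called up to 21 with the preset one, but mix the groups and keep part of their difference. The list calls that held with an estimated correlation were acute phase proteins at 3, 6 and 12 h against sham, and G1/S cyclins at 12 h against sham, 6 h and 3 h. In every list that camera called the median, the mean and the camera test had the same sign.

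**Figure D1:**
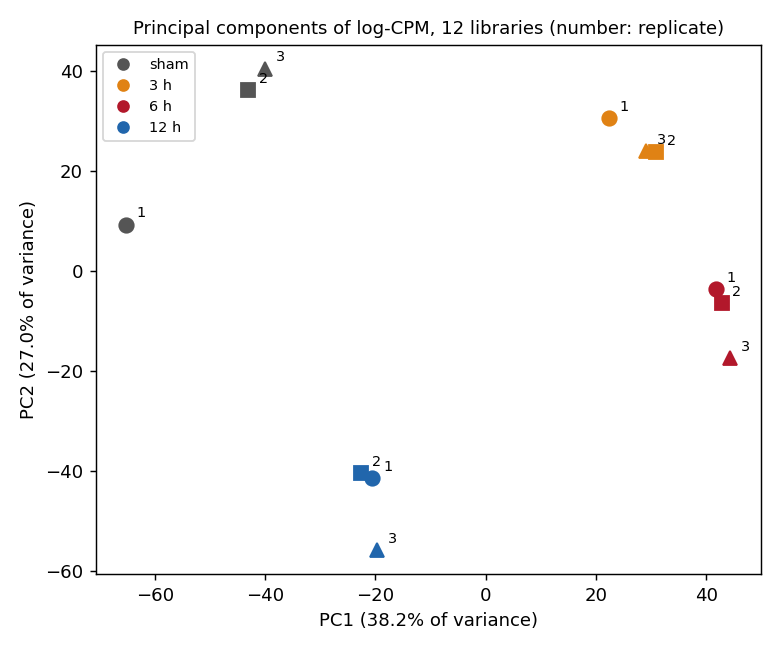
Principal components 1 (38.2% of variance) and 2 (27.0%) of log CPM for the 12 libraries, each point a library labelled with its replicate number and coloured by group. Sham replicate 1 lies apart from sham replicates 2 and 3, and the libraries of the other groups lie close to their own group.

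The comparison of 3 h with sham asks which genes respond first. Acute phase transcripts, which the liver makes in response to inflammatory cytokines, rose almost without exception: 26 of 29 tested genes rose, or 27 adjusted over the list alone. Their median log2 difference was 1.88 (camera adjusted p = 6.47e-31, adjusted p = 0.011 with an estimated correlation). Lcn2 (ENSMUSG00000026822) encodes the secreted siderophore-binding protein lipocalin 2. Its level rose from 0.739 ± 0.281 FPKM in sham to 297 ± 119, a log2 difference of 8.59 ± 0.45 (SE, edgeR adjusted p = 1.47e-07). The serum amyloid transcripts Saa2 (8.51 ± 0.43) and Saa1 (6.28 ± 0.43) and the metallothionein Mt1 (8.01 ± 0.50), a metal-binding protein, rose by comparable steps. Saa1 and Saa2, like Mt1 and Mt2, are close copies whose reads may be shared. Mt2 had 3 counts over the sham libraries against 1581 at 3 h, a ratio of 615 with a 95% counting interval of 210.2 to 2987. Cdkn1a (ENSMUSG00000023067), encoding the cell cycle inhibitor p21, rose from 0.727 ± 0.410 to 61.6 ± 11.8 FPKM (6.35 ± 0.34, edgeR adjusted p = 1.47e-07).

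Targets of IL-6 and STAT3, the cytokine pathway that primes hepatocytes, moved with them: 10 of 14 tested genes rose and 1 fell, or 11 and 1 adjusted over the list alone. The list had a median log2 difference of 1.34 (camera adjusted p = 1.19e-07, adjusted p = 0.0551 with an estimated correlation). Its largest members were the interleukin 1 receptor Il1r1 (4.005 ± 0.30), the feedback inhibitor Socs3 (3.96 ± 0.40), the transcription factor Cebpd (3.06 ± 0.53) and the oncostatin M receptor Osmr (2.58 ± 0.23). Socs3 (ENSMUSG00000053113) went from 2.09 ± 1.42 FPKM in sham to 33.6 ± 3.07 (edgeR adjusted p = 1.88e-05). Among immediate early genes, which are switched on without new protein synthesis, 23 of 33 tested genes rose and 1 fell, or 24 and 2 adjusted over the list alone. This gave a median log2 difference of 1.30 (camera adjusted p = 1.71e-10, adjusted p = 0.254 with an estimated correlation). These included Gadd45g (4.05), Fos (3.46), Junb (2.73) and Klf4 (2.46). Fos, a subunit of the transcription factor AP-1, was at 8.63, 1.79 and 1.30 FPKM in the 3 h libraries against 0.343 ± 0.150 in sham. Its difference was 2.13 without 3 h replicate 1. Its partner Jun rose by 1.52 ± 0.47 (edgeR adjusted p = 0.0334). That call was lost without any of the 3 h libraries, with 1.60, 1.38 and 1.59 without 3 h replicates 1, 2 and 3. The growth regulator Myc rose from 1.08 ± 0.580 to 4.48 ± 0.597 FPKM (edgeR adjusted p = 0.00313). Atf3, a stress-induced transcription factor, differed by 0.97 ± 0.59 and did not pass the test (edgeR adjusted p = 0.277). Of the NF-kB and cytokine genes, not called as a list (camera adjusted p = 0.128), 6 of 17 tested genes rose and 2 fell, or 6 and 3 adjusted over the list alone. Even so, the neutrophil attractant Cxcl1 rose by 5.62 ± 0.63 and the monocyte attractant Ccl2 by 2.52 ± 0.47. Targets of p53, to which Cdkn1a belongs, were likewise not called (camera adjusted p = 0.16), and 6 of 15 tested genes rose and 3 fell, or 6 and 4 adjusted over the list alone. The pro-apoptotic Bbc3 fell by 2.77.

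Metabolic genes went both ways at 3 h. Cholesterol synthesis genes fell together: 15 of 25 tested genes fell, or 16 adjusted over the list alone. The median log2 difference was -0.93 (camera adjusted p = 6.37e-07, adjusted p = 0.31 with an estimated correlation). Examples were Insig1 (-2.89), Fdps (-2.15) and Mvd (-1.99). Cyp7a1 (ENSMUSG00000028240) encodes the rate-limiting enzyme of bile acid synthesis. Its level fell from 20.9 ± 16.3 to 1.72 ± 0.899 FPKM, a log2 difference of -3.65 ± 0.60 (edgeR adjusted p = 0.000856). Lipid droplet and lipid uptake genes rose: 8 of 16 tested genes rose, or 8 adjusted over the list alone. As a list, the median log2 difference was 1.31 (camera adjusted p = 0.00229, adjusted p = 0.31 with an estimated correlation). Among them were the perilipins Plin5 (2.90) and Plin4 (2.84) and the phosphatidate phosphatase Lpin1 (2.58). The median was 0.73 without 3 h replicate 2. Of the genes of the urea cycle and amino acid breakdown, 10 of 26 tested genes rose, or 11 adjusted over the list alone. Over the whole list the median log2 difference was 0.40 (camera adjusted p = 2.26e-05, adjusted p = 0.267 with an estimated correlation). The call was lost after quantile normalization (median 0.13). Examples were the serine dehydratase Sds (2.03) and the lysine-degrading enzyme Aass (1.74). Igfbp1 (ENSMUSG00000020429) encodes a secreted binding protein of insulin-like growth factors and is an early gene of liver regeneration. It rose from 64.6 ± 8.73 to 518 ± 109 FPKM (2.96 ± 0.30, edgeR adjusted p = 1.79e-05). Dbp (ENSMUSG00000059824), an output transcription factor of the circadian clock, fell from 6.46 ± 4.10 to 0.276 ± 0.0495 FPKM (-4.58 ± 0.52, edgeR adjusted p = 5.02e-05). Of the clock genes, 1 of 19 tested genes rose and 8 fell, or 1 and 9 adjusted over the list alone. Across tested members the median log2 difference was -0.36 (camera adjusted p = 0.0251, adjusted p = 0.157 with an estimated correlation). These included Per3 (-3.62), Nr1d1 (-2.63) and Nr1d2 (-2.31). The clock median was -0.54 and -0.49 without sham replicates 1 and 3, the latter with the call lost. It was also lost with library totals (median -0.53), TPM (-0.51) and quantile normalization (-0.28). Arrdc3, an arrestin-domain protein, Clec2h, a C-type lectin, and Kcnk5, a potassium channel, completed the 5 largest falls among protein-coding genes with 5 FPKM or more in sham and no overlap between the groups, at -3.90, -3.87 and -3.26.

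Genes of protein synthesis had begun to rise at 3 h. Of those of ribosome biogenesis, 27 of 45 tested genes rose and 1 fell, or 31 and 1 adjusted over the list alone. For the list the median log2 difference was 0.60 (camera adjusted p = 1.09e-11, adjusted p = 0.106 with an estimated correlation). Members included Rrp12 (1.57), Nop58 (1.44) and Heatr1 (1.40). Cell cycle lists were not called: of G1 to S regulators (camera adjusted p = 0.223) 3 of 16 tested genes rose and 6 fell, or 3 and 6 adjusted over the list alone, and of DNA replication genes (camera adjusted p = 0.221) 1 of 23 tested genes rose and 2 fell, or 1 and 2 adjusted over the list alone. Translation factors and aminoacyl-tRNA synthetases were higher, and 7 of 37 tested genes rose, or 5 adjusted over the list alone. A median log2 difference of 0.25 was found (camera adjusted p = 0.000532, adjusted p = 0.267 with an estimated correlation). Of metallothionein, iron and zinc handling genes, which include Mt1 and Mt2, 8 of 20 tested genes rose and 1 fell, or 8 and 1 adjusted over the list alone. At list level the median log2 difference was 0.42 (camera adjusted p = 0.000262, adjusted p = 0.118 with an estimated correlation). Ccnd1, the cyclin that drives entry into the cell cycle, rose by 1.10 ± 0.30 (edgeR adjusted p = 0.0197). Its call was lost at 0.97 without 3 h replicate 2, 0.89 as TPM and 0.91 with library totals. Hgf, the hepatocyte growth factor, rose by 0.93 ± 0.29 (edgeR adjusted p = 0.0356). The Hgf call was lost at 0.92 and 0.67 without sham replicates 2 and 3, and 0.70 and 0.96 without 3 h replicates 2 and 3. The replication helicase subunit Mcm5 (0.13 ± 0.40, edgeR adjusted p = 0.855) and albumin, Alb (0.13 ± 0.13, edgeR adjusted p = 0.527), did not pass the test. Mki67, a proliferation marker, lay at 0.0581 to 0.593 FPKM over the 12 libraries, under the level tested. Of 18 neutrophil markers 6 were tested, all but Hdc under a mean of 1 FPKM in sham, so the filter favoured rises. Of these 5 rose, or 6 adjusted over the list alone. The median log2 difference was 3.00 (camera adjusted p = 6.27e-06, adjusted p = 0.0551 with an estimated correlation). Beside Lcn2, also in the acute phase list, these included S100a9 (3.29) and S100a8 (2.72), and Retnlg with 43 counts against 3 in sham, a ratio of 16.7 (counting interval 5.36 to 84.3). Of monocyte and macrophage markers, 5 of 7 tested genes rose, or 5 adjusted over the list alone. Their median log2 difference was 0.78 (camera adjusted p = 0.000402, adjusted p = 0.118 with an estimated correlation). They included Cd14 (3.13) and Plac8 (1.14). The monocyte median was 1.23 without sham replicate 3. Red blood cell markers were not called by camera (median 0.79, camera adjusted p = 0.0688) but were higher by fry (adjusted p = 0.0102), and 2 of 6 tested genes rose, or 4 adjusted over the list alone. Of liver endothelial cell markers, such as the hyaluronan receptor Lyve1 (2.26), 6 of 19 tested genes rose, or 7 adjusted over the list alone. The list had a median log2 difference of 0.48 (camera adjusted p = 0.000897, adjusted p = 0.339 with an estimated correlation). Of stellate cell and fibroblast markers, such as the growth factor receptor Pdgfra (1.53), 5 of 18 tested genes rose, or 8 adjusted over the list alone. This gave a median log2 difference of 0.52 (camera adjusted p = 0.00128, adjusted p = 0.339 with an estimated correlation).

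In all, 1123 genes were higher and 1345 lower at 3 h than in sham by edgeR, 577 and 602 of them by 2-fold or more. The groups did not overlap for 36.4% of genes, against 10% by chance. In simulated data of this comparison the test called 3 of 50 genes changed 1.5-fold, 35 of 50 changed 2-fold and 41 of 50 changed 4-fold. The share of calls that were higher, 45.5% here, was 23.5% with TPM and 25% with library totals, which moved the median of all genes by -0.20, and 884 genes were lower without 3 h replicate 3. Cytosolic ribosomal proteins, hypoxia and glycolysis genes, the nuclear-encoded respiratory chain and secreted liver proteins were called higher as lists, but not without sham replicate 1 (medians 0.08, 0.26, 0.07 and 0.12). These had adjusted p = 0.611, 0.31, 0.649 and 0.31 with an estimated correlation, and the secreted proteins a median of -0.16 after quantile normalization, -0.05 with TPM and -0.023 with library totals. The respiratory chain had a median of -0.0032 with TPM, lost its call at 0.17 and 0.14 without 3 h replicates 1 and 3 and was at 0.29 without sham replicate 3 and 0.32 without 3 h replicate 2. Fatty acid oxidation (0.45) and glucose output (0.54) were called higher too, with adjusted p = 0.545 and 0.22 with an estimated correlation. Fatty acid oxidation was at 0.28 without sham replicate 1 and 0.29 without 3 h replicate 2, and glucose output at 0.35 without sham replicate 1 and not called after quantile normalization (0.44).

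**Figure D2:**
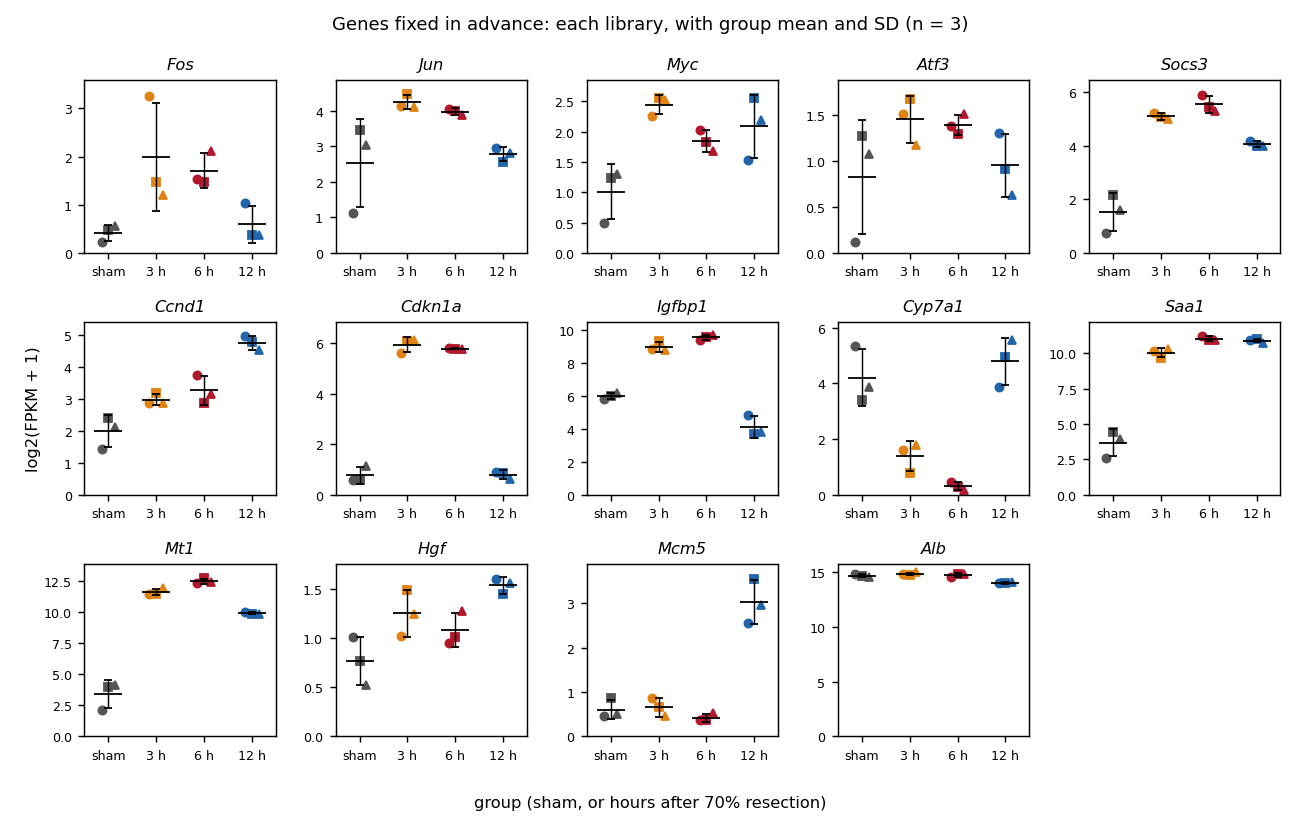
Expression as log2(FPKM + 1) of 14 genes fixed in advance, by group (sham, and 3, 6 and 12 h after 70% resection), with each library as a symbol for its replicate and the bar as group mean ± SD (n = 3). Cdkn1a and Igfbp1 were high at 3 h and 6 h and back at or under the sham level at 12 h, Cyp7a1 showed the opposite course, and Mcm5 rose at 12 h.

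The comparison of 6 h with sham asks which programs hold when the response is under way. The acute phase response was broader still: 28 of 29 tested genes rose, or 28 adjusted over the list alone. The median log2 difference was 2.80 (camera adjusted p = 1.86e-27, adjusted p = 0.0164 with an estimated correlation). Lcn2 reached 955 ± 336 FPKM (log2 difference 10.29 ± 0.48, edgeR adjusted p = 3.14e-08). Saa2 reached 2051 ± 372 (9.55 ± 0.45), Saa1 2094 ± 239 (7.26 ± 0.45) and Mt1 5597 ± 809.8 (8.88 ± 0.52). The Saa and Mt pairs are again uncertain because reads may be shared. Mt2 had 1185 counts at 6 h against 3 in sham, a ratio of 493 with a counting interval of 168 to 2392. A2m encodes the protease inhibitor alpha-2-macroglobulin. It was at 13.7 ± 15.3 FPKM against 0.0466 ± 0.00615 in sham (8.14 ± 1.04, edgeR adjusted p = 5.49e-05). Of this, 6 h replicate 3 held 31.4 FPKM and the others 4.58 and 5.29. Of the IL-6 and STAT3 targets, 9 of 14 tested genes rose and 1 fell, or 9 and 1 adjusted over the list alone. As a list, the median log2 difference was 1.22 (camera adjusted p = 4.21e-05, adjusted p = 0.115 with an estimated correlation). Examples were Socs3 (4.45), Il1r1 (4.33) and Osmr (3.32). Of the immediate early genes, 21 of 33 tested genes rose and 2 fell, or 23 and 4 adjusted over the list alone. Over the whole list the median log2 difference was 1.22 (camera adjusted p = 7.13e-06, adjusted p = 0.449 with an estimated correlation). Among them were Gadd45g (3.95), Ier3 (3.45), Btg2 (2.90) and Fos (2.71). The Fos call was lost at 2.05 without both sham replicate 1 and 6 h replicate 3. Myc rose by 1.24 ± 0.40 (edgeR adjusted p = 0.0294). The Myc call was lost at 0.85 without sham replicate 1, and 1.10 and 1.25 without 6 h replicates 1 and 2, at 0.81 as TPM and at 0.91 with library totals. Jun (1.24 ± 0.47, edgeR adjusted p = 0.0536) and Atf3 (0.86 ± 0.60, edgeR adjusted p = 0.298) did not pass. Jun passed at 0.76 and 1.78 without sham replicates 1 and 2. Cdkn1a stayed at 54.5 ± 1.18 FPKM (6.19 ± 0.34) and Igfbp1 reached 765 ± 70.4 (3.54 ± 0.30, edgeR adjusted p = 2.51e-06).

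Genes of protein synthesis and folding rose widely at 6 h. Ribosome biogenesis showed the most members changed: 36 of 45 tested genes rose, or 38 adjusted over the list alone. Across tested members the median log2 difference was 0.90 (camera adjusted p = 9.16e-13, adjusted p = 0.115 with an estimated correlation). These included Rrp12 (2.06), Nop58 (2.02) and Polr1e (1.60). Translation factors and aminoacyl-tRNA synthetases followed: 25 of 37 tested genes rose, or 27 adjusted over the list alone. For the list the median log2 difference was 0.52 (camera adjusted p = 1.06e-08, adjusted p = 0.115 with an estimated correlation). Members included Eif1a (1.61), Eif6 (1.49) and Wars (1.46). The unfolded protein response and chaperones of the endoplasmic reticulum rose too: 12 of 20 tested genes rose, or 13 adjusted over the list alone. A median log2 difference of 0.63 was found (camera adjusted p = 1.96e-06, adjusted p = 0.342 with an estimated correlation). They included the secreted stress factors Creld2 (2.59) and Manf (2.14) and the ubiquitin ligase Syvn1 (1.97). Cytosolic ribosomal proteins themselves moved little, with a called median of 0.21 (camera adjusted p = 0.00744, adjusted p = 0.765 with an estimated correlation). It was 0.01 without sham replicate 1 and changed sign with library totals (-0.10) and TPM (-0.08). Ccnd1 rose to 8.91 ± 3.17 FPKM (1.49 ± 0.31, edgeR adjusted p = 0.00199). Mcm5 had a difference of -0.66 ± 0.43 (edgeR adjusted p = 0.263). Hgf did not pass at 0.62 ± 0.29 (edgeR adjusted p = 0.119) but did at 0.95 without sham replicate 1. Among DNA replication genes, 6 of 23 tested genes fell, or 6 adjusted over the list alone. At list level the median log2 difference was -0.32 (camera adjusted p = 0.0355, adjusted p = 0.672 with an estimated correlation). The call was lost at medians of -0.36 without sham replicate 1, and -0.31 and -0.46 without 6 h replicates 1 and 2 and kept at -0.56 without 6 h replicate 3. It was lost too at -0.63 with library totals.

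Lipid and bile acid synthesis fell at 6 h. Of the cholesterol synthesis genes, 19 of 25 tested genes fell, or 19 adjusted over the list alone. Taking all tested members, the median log2 difference was -1.29 (camera adjusted p = 3.34e-08, adjusted p = 0.342 with an estimated correlation). Examples were Insig1 (-2.66), Hmgcs1 (-2.52) and Sc5d (-2.50). Of the fatty acid synthesis genes, under the regulators SREBP1c and ChREBP, 1 of 20 tested genes rose and 11 fell, or 1 and 11 adjusted over the list alone. Their median log2 difference was -1.27 (camera adjusted p = 0.00012, adjusted p = 0.383 with an estimated correlation). Among them were the regulator Srebf1 (-2.81) and the citrate lyase Acly (-2.06). In bile acid synthesis and transport, 1 of 21 tested genes rose and 11 fell, or 1 and 13 adjusted over the list alone. The list had a median log2 difference of -0.80 (camera adjusted p = 0.00582, adjusted p = 0.319 with an estimated correlation). Cyp7a1 fell to 0.237 ± 0.124 FPKM (-6.47 ± 0.74, edgeR adjusted p = 2.29e-05), and the nuclear receptor Nr0b2 (-1.79) and the canalicular transporter Abcc2 (-1.24) were lower too. Hsd3b5 encodes a male-biased steroid dehydrogenase. It fell from 212 ± 8.15 to 2.29 ± 0.927 FPKM (-6.56 ± 0.52), as did its close copy Hsd3b2 (-5.19 ± 0.39), both uncertain because reads may be shared. Genes of pericentral hepatocytes, the cells around the central vein, were lower as a list, and 1 of 24 tested genes rose and 10 fell, or 3 and 11 adjusted over the list alone. This gave a median log2 difference of -0.49 (camera adjusted p = 0.00744, adjusted p = 0.474 with an estimated correlation). These included Notum (-1.96) and Rnf43 (-1.74). Dbp was at 0.251 ± 0.122 FPKM (-4.69 ± 0.53), and Clec2h, with 10 counts against 845 in sham, was 67.8-fold lower (counting interval 36.7 to 142). Of the clock genes, 1 of 19 tested genes rose and 9 fell, or 2 and 9 adjusted over the list alone. The median log2 difference was -0.75 (camera adjusted p = 0.0399, adjusted p = 0.219 with an estimated correlation). The clock call was lost at medians of -0.73 and -0.89 without sham replicates 1 and 3, and -0.75 without 12 h replicate 3, and with library totals at -1.06. Fatty acid oxidation genes and PPAR alpha targets were called higher, and 12 of 34 tested genes rose and 3 fell, or 14 and 3 adjusted over the list alone. As a list, the median log2 difference was 0.69 (camera adjusted p = 0.00744, adjusted p = 0.672 with an estimated correlation). Their call was lost at medians of 0.57 without sham replicate 1 and 0.46 without 6 h replicate 1. Alb differed by 0.03 ± 0.13 and did not pass (edgeR adjusted p = 0.888), but as TPM it was called lower, at -0.30.

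Tested white cell markers were higher at 6 h. Of the neutrophil markers, with S100a9 at 3.19, 4 of 6 tested genes rose, or 4 adjusted over the list alone. Over the whole list the median log2 difference was 2.94 (camera adjusted p = 0.000779, adjusted p = 0.115 with an estimated correlation). Of the 18 monocyte markers 7 were tested, with the endotoxin receptor Cd14 at 3.19. Of the 7 tested genes 5 rose, against 5 risen and 1 fallen adjusted over the list alone. Across tested members the median log2 difference was 0.93 (camera adjusted p = 0.0121, adjusted p = 0.319 with an estimated correlation). Without sham replicate 3 the monocyte median was 1.42, and without both sham replicate 1 and 6 h replicate 3 the call was lost at 0.59. In total 1924 genes were higher and 2080 lower at 6 h than in sham by edgeR, 826 and 1031 of them by 2-fold or more. The groups did not overlap for 43.9% of genes, against 10% by chance. The share of calls that were higher, 48.1% here, was 22.0% with TPM or library totals. Library totals moved the median of all genes from -0.0089 to -0.32. Of metallothionein, iron and zinc handling genes, 8 of 20 tested genes rose and 3 fell, or 8 and 4 adjusted over the list alone. For the list the median log2 difference was 0.15 (camera adjusted p = 0.0271, adjusted p = 0.342 with an estimated correlation). Their list was not called at 0.13 without sham replicate 1 and 0.12 without 6 h replicate 1, was at 0.25 without sham replicate 2 and 0.26 without 6 h replicate 3, and its median changed sign with TPM (-0.16) and library totals (-0.17).

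The comparison of 12 h with sham asks which programs precede cell division. Genes of DNA replication, little used in a resting liver, rose together: 18 of 23 tested genes rose, or 18 adjusted over the list alone. A median log2 difference of 1.77 was found (camera adjusted p = 5.99e-11, adjusted p = 0.214 with an estimated correlation). Mcm5 went from 0.531 ± 0.241 to 7.44 ± 2.95 FPKM (3.79 ± 0.38, edgeR adjusted p = 2.06e-05). The chromatin factor Uhrf1 (5.51) and the helicase subunits Mcm2 (3.44) and Mcm6 (3.24) rose with it. Cyclins and regulators of the G1 to S step followed: 11 of 16 tested genes rose, or 11 adjusted over the list alone. At list level the median log2 difference was 0.86 (camera adjusted p = 4.11e-06, adjusted p = 0.0146 with an estimated correlation). Members included Ccne1 (3.74), Cdt1 (2.76) and Rbl1 (2.15). Ccnd1 (ENSMUSG00000070348) rose from 3.11 ± 1.32 to 26.2 ± 4.17 FPKM (3.06 ± 0.32, edgeR adjusted p = 2.58e-05). Cdkn1a had returned to 0.745 ± 0.197 FPKM, 0.02 ± 0.32 from sham (edgeR adjusted p = 0.978). Myc (1.65 ± 0.40, edgeR adjusted p = 0.00796) and Hgf (1.40 ± 0.29, edgeR adjusted p = 0.0031) were higher than in sham. Fos (0.66 ± 0.79), Jun (-0.06 ± 0.46) and Atf3 (0.14 ± 0.61) did not pass (edgeR adjusted p = 0.574, 0.939 and 0.892), although Jun passed at -0.55 without sham replicate 1. The immediate early list was not called at 12 h (camera adjusted p = 0.343), and 2 of 33 tested genes rose and 6 fell, or 2 and 6 adjusted over the list alone.

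The acute phase response persisted at 12 h: 27 of 29 tested genes rose and 1 fell, or 28 and 1 adjusted over the list alone. Taking all tested members, the median log2 difference was 2.28 (camera adjusted p = 7.86e-26, adjusted p = 0.0146 with an estimated correlation). Lcn2 was at 613 ± 122 FPKM (9.67 ± 0.47), Saa2 at 1878 ± 243 (9.45 ± 0.45), Saa1 at 1886 ± 148 (7.12 ± 0.45) and Mt1 at 949 ± 54.2 (6.34 ± 0.47). Reads of the Saa and of the Mt genes may be shared. Socs3 was still raised at 15.7 ± 1.26 FPKM (2.89 ± 0.38, edgeR adjusted p = 0.00016). Ly6d, a cell surface protein of the Ly6 family, rose from 0.406 ± 0.436 to 42.1 ± 10.5 FPKM (6.62 ± 0.82, edgeR adjusted p = 9.63e-05). Of the ribosome biogenesis genes, with the nucleolar Nop58 at 1.47, 25 of 45 tested genes rose, or 30 adjusted over the list alone. Their median log2 difference was 0.56 (camera adjusted p = 4.17e-09, adjusted p = 0.2 with an estimated correlation). Of the translation factors and aminoacyl-tRNA synthetases, 18 of 37 tested genes rose and 2 fell, or 22 and 2 adjusted over the list alone. The list had a median log2 difference of 0.42 (camera adjusted p = 1.26e-05, adjusted p = 0.21 with an estimated correlation). The unfolded protein response and chaperones remained higher too: 11 of 20 tested genes rose, or 12 adjusted over the list alone. This gave a median log2 difference of 0.61 (camera adjusted p = 4.3e-06, adjusted p = 0.335 with an estimated correlation). They included the chaperone Hspa5 (1.46). Interferon-stimulated genes were lower: 8 of 22 tested genes fell, or 8 adjusted over the list alone. The median log2 difference was -0.71 (camera adjusted p = 0.007, adjusted p = 0.673 with an estimated correlation). Examples were Rsad2 (-2.14) and Oas2 (-1.30). The interferon call was lost at a median of -0.61 without sham replicate 1. Neutrophil markers such as S100a9 (2.56) were called higher, and 3 of 6 tested genes rose, or 3 adjusted over the list alone. As a list, the median log2 difference was 1.45 (camera adjusted p = 0.0237, adjusted p = 0.229 with an estimated correlation). The neutrophil call was lost at 1.30 without sham replicate 1.

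Hepatocyte metabolism was lower at 12 h in several groups. Of the fatty acid synthesis genes, 14 of 20 tested genes fell, or 16 adjusted over the list alone. Over the whole list the median log2 difference was -1.22 (camera adjusted p = 9.66e-09, adjusted p = 0.21 with an estimated correlation). Among the genes of bile acid synthesis and transport, 1 of 21 tested genes rose and 11 fell, or 1 and 11 adjusted over the list alone. Across tested members the median log2 difference was -0.67 (camera adjusted p = 0.000211, adjusted p = 0.2 with an estimated correlation). Among them were the bile salt pump Abcb11 (-2.04) and the sterol hydroxylase Cyp8b1 (-1.89). Cyp7a1, however, was back at 29.8 ± 16.1 FPKM (0.50 ± 0.53, edgeR adjusted p = 0.513) and was called higher at 1.34 without sham replicate 1. Among cytochrome P450 and drug metabolism genes, 3 of 32 tested genes rose and 18 fell, or 4 and 19 adjusted over the list alone. For the list the median log2 difference was -0.77 (camera adjusted p = 9.3e-05, adjusted p = 0.214 with an estimated correlation). These included Cyp1a2 (-1.78) and Cyp4f14 (-1.68). Coq8a encodes a kinase-like protein of coenzyme Q synthesis. It fell from 84.7 ± 14.6 to 2.74 ± 1.17 FPKM (-4.96 ± 0.32, edgeR adjusted p = 6.3e-07). The fatty acid elongase Elovl3 averaged 293 FPKM in sham and 12.98 at 12 h (-4.50 ± 0.27, edgeR adjusted p = 4.87e-07). Pitx3, a transcription factor, had 3 counts at 12 h against 448 in sham and was 149.8-fold lower (counting interval 50.9 to 729). It lies 377 bases from Elovl3 on the opposite strand and the strand used in counting is not stated, so the reads may not be its own. The ubiquitin ligase Rnf125 fell by 3.85 ± 0.44, from 181 FPKM in sham replicate 1 and 62.5 and 56.5 in the others to 6.94 ± 0.378. Igfbp1 fell below the sham level, to 17.7 ± 9.16 FPKM (-1.88 ± 0.29, edgeR adjusted p = 0.000423). Alb fell by 0.65 ± 0.13 (edgeR adjusted p = 0.00312), a call lost after quantile normalization (difference -0.24).

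Red cell, Kupffer cell and stellate cell marker lists were not called at 12 h (camera adjusted p = 0.052, 0.177 and 0.485), though red cell and Kupffer cell markers were lower by fry (adjusted p = 0.00254 and 0.0424). Of red cell markers 1 of 6 tested genes rose and 4 fell, or 1 and 5 adjusted over the list alone. Of Kupffer cell markers 2 of 13 tested genes rose and 5 fell, or 3 and 6 adjusted over the list alone. Of stellate cell markers 3 of 18 tested genes rose and 3 fell, or 3 and 4 adjusted over the list alone. Of 19 markers of neighbouring tissue 3 were tested (Cfd, Car3 and Cela1), too few to stand for it. All 3 fell, or 3 adjusted over the list alone (median log2 difference -2.44, camera adjusted p = 0.00407, adjusted p = 0.153 with an estimated correlation). Altogether 1547 genes were higher and 1751 lower at 12 h than in sham by edgeR, 556 and 746 of them by 2-fold or more. Values of the groups did not overlap for 38.6% of genes, against 10% by chance. The counts were 2597 and 2666 without sham replicate 1 and 981 and 1131 without 12 h replicate 3. Calls by camera for the nuclear-encoded respiratory chain (median -0.25 without sham replicate 3), endothelial cells (-0.37 and -0.26 without sham replicates 1 and 3, and -0.29 without 12 h replicate 1; -0.36 with all libraries and -0.56 without 12 h replicate 2, where the call was kept), fatty acid oxidation (0.23 without sham replicate 1 and 0.21 without 12 h replicate 1) and amino acid breakdown (-0.53, -0.55 and -0.56 without sham replicates 1, 2 and 3, -0.55 without 6 h replicate 2, and -0.50 and -0.57 without 12 h replicates 1 and 2) were lost, and these lists had adjusted p = 0.74, 0.656, 0.747 and 0.656 with an estimated correlation.

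**Figure D3:**
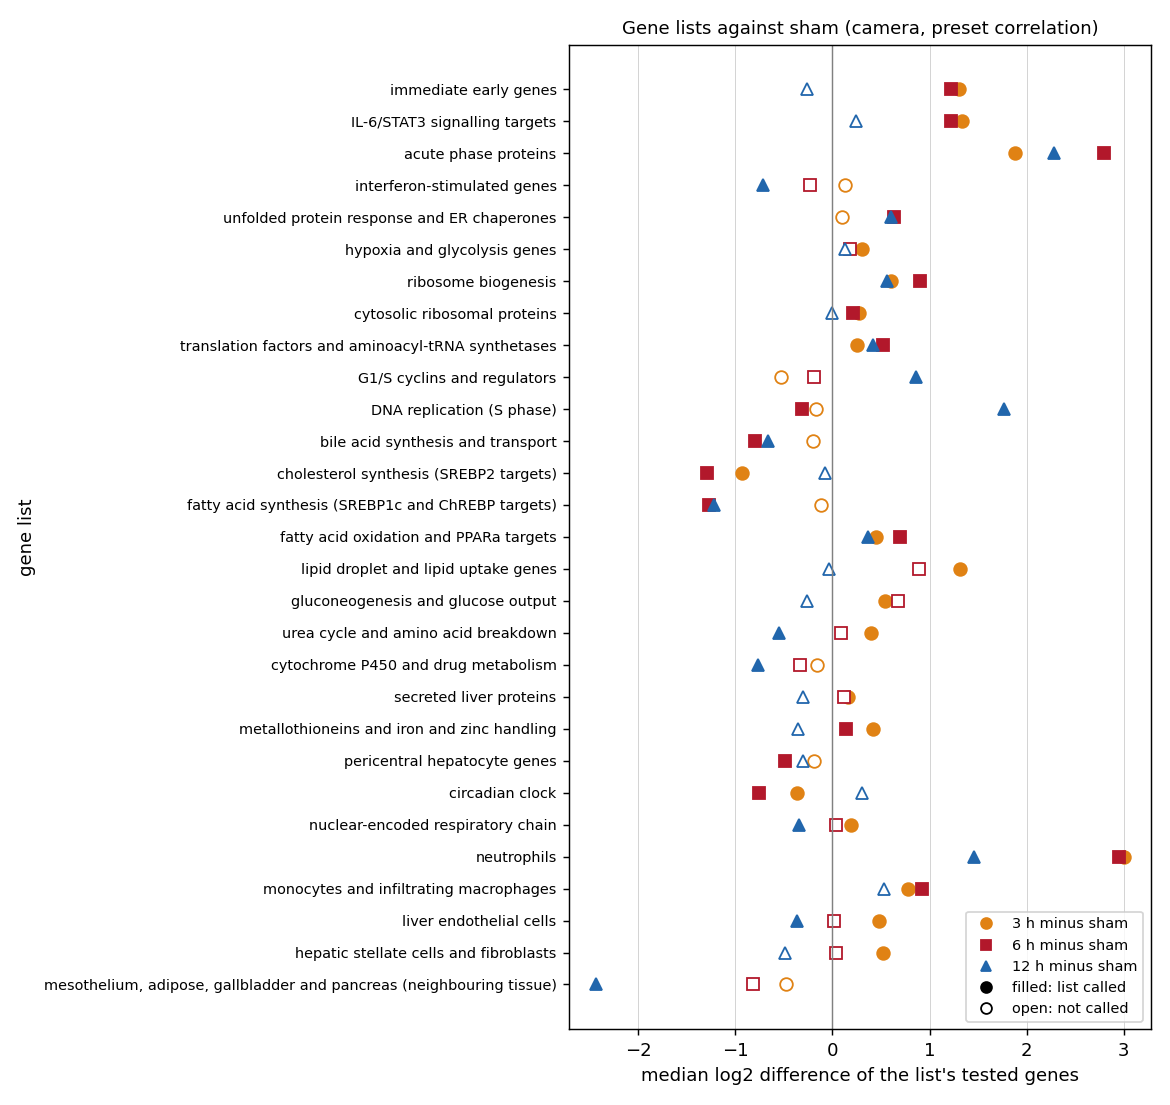
Median log2 difference against sham (x axis) of the tested genes of each list called at 3, 6 or 12 h (y axis), with circles for 3 h, squares for 6 h and triangles for 12 h, filled where camera with the preset correlation called the list. Acute phase proteins were called at all 3 times (medians 1.88, 2.80 and 2.28) and DNA replication genes were higher at 12 h (1.77).

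The comparison of 6 h with 3 h asks how the first response develops. Acute phase transcripts kept rising: 17 of 29 tested genes rose, or 22 adjusted over the list alone. At list level the median log2 difference was 0.92 (camera adjusted p = 9.8e-14, adjusted p = 0.14 with an estimated correlation). Members included the pentraxin Apcs (1.81), the interleukin 1 antagonist Il1rn (1.76) and Lcn2 (1.71). The unfolded protein response and chaperones rose over the same hours: 10 of 20 tested genes rose, or 13 adjusted over the list alone. Taking all tested members, the median log2 difference was 0.64 (camera adjusted p = 5.12e-10, adjusted p = 0.295 with an estimated correlation). They included Dnajb9 (2.57), Syvn1 (2.09) and Creld2 (1.70). Of the translation factors and aminoacyl-tRNA synthetases, 8 of 37 tested genes rose, or 12 adjusted over the list alone. Their median log2 difference was 0.32 (camera adjusted p = 6.16e-08, adjusted p = 0.295 with an estimated correlation). Of the ribosome biogenesis genes, 5 of 45 tested genes rose, or 13 adjusted over the list alone. The list had a median log2 difference of 0.20 (camera adjusted p = 0.000731, adjusted p = 0.403 with an estimated correlation). Without 3 h replicate 1 their median was 0.12. Fatty acid synthesis fell: 9 of 20 tested genes fell, or 13 adjusted over the list alone. This gave a median log2 difference of -0.88 (camera adjusted p = 3.94e-09, adjusted p = 0.295 with an estimated correlation). The lipogenic regulator Thrsp went from 262 ± 129 FPKM at 3 h to 36.0 ± 16.3 at 6 h (-2.86 ± 0.39, edgeR adjusted p = 0.00111). In bile acid synthesis and transport, 1 of 21 tested genes rose and 3 fell, or 1 and 8 adjusted over the list alone. The median log2 difference was -0.40 (camera adjusted p = 0.000937, adjusted p = 0.295 with an estimated correlation). In cytochrome P450 and drug metabolism, with the omega-hydroxylase Cyp4f14 at -0.74, 4 of 32 tested genes fell, against 7 fallen and 2 risen adjusted over the list alone. As a list, the median log2 difference was -0.31 (camera adjusted p = 0.000595, adjusted p = 0.306 with an estimated correlation). Several cell type lists were lower at 6 h than at 3 h. Of Kupffer cell markers, 2 of 13 tested genes fell, or 4 adjusted over the list alone. Over the whole list the median log2 difference was -0.48 (camera adjusted p = 0.00724, adjusted p = 0.398 with an estimated correlation). Of endothelial cell markers, 3 of 19 tested genes fell, or 3 adjusted over the list alone. Across tested members the median log2 difference was -0.51 (camera adjusted p = 7.62e-05, adjusted p = 0.398 with an estimated correlation). Of red blood cell markers, 3 of 6 tested genes fell, or 4 adjusted over the list alone. For the list the median log2 difference was -0.90 (camera adjusted p = 0.0118, adjusted p = 0.297 with an estimated correlation). Stellate cells (-0.33), pericentral genes (-0.32) and NRF2 targets (-0.40) were called lower too, with adjusted p = 0.619, 0.564 and 0.306 with an estimated correlation. So were cholesterol synthesis (-0.26) and the respiratory chain (-0.18), with adjusted p = 0.819 and 0.819 with an estimated correlation. The cholesterol call was lost at -0.12 without 3 h replicate 1. The respiratory chain call was lost at -0.12 and -0.13 without 3 h replicates 1 and 3, and -0.14 without 6 h replicate 2 and after quantile normalization (-0.05), and the median was -0.31 without 3 h replicate 2. The stellate cell call was lost at -0.27 without 3 h replicate 2 and the median was -0.54 without 3 h replicate 3. The pericentral call was lost at -0.13 without 6 h replicate 3, and that for NRF2 targets at -0.42 and -0.25 without 3 h replicates 1 and 3, and -0.34 without 6 h replicate 2 and after quantile normalization (-0.20).

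Hsd3b5 (-3.97 ± 0.47) and Coq8a (-3.07 ± 0.29) fell further between 3 h and 6 h (edgeR adjusted p = 0.000528 and 0.000131). Arfgap3, which regulates vesicle coats at the Golgi, rose from 1.07 ± 0.159 to 9.59 ± 1.41 FPKM (3.17 ± 0.21, edgeR adjusted p = 8.85e-06). A2m rose by 3.52 ± 0.74 (edgeR adjusted p = 0.0119), a value that was 2.04 without 6 h replicate 3 and lost its call at 3.20 without 3 h replicate 1. The major urinary protein gene Mup8, uncertain because the Mup genes are close copies, was at 177, 122 and 3.36 FPKM in the 6 h libraries against 2.29 ± 0.696 at 3 h (5.48 ± 1.36, edgeR adjusted p = 0.0259). Its call was lost at 5.24, 5.57 and 5.64 without 3 h replicates 1, 2 and 3, and 4.80 and 5.31 without 6 h replicates 1 and 2. Cyp7a1 fell by 2.83 ± 0.73 (edgeR adjusted p = 0.0318). The Cyp7a1 call was lost at -2.69 and -2.51 without 3 h replicates 1 and 3, and -3.28, -2.76 and -2.53 without 6 h replicates 1, 2 and 3. Among the other fixed genes, Fos, Jun, Myc, Atf3, Socs3, Ccnd1, Cdkn1a, Igfbp1, Saa1, Mt1, Hgf, Mcm5 and Alb did not pass the test between 3 h and 6 h, with differences from -0.78 for Mcm5 to 0.98 for Saa1. Without sham replicate 1 Saa1 passed at 0.98 and Mt1 at 0.87. Fewer genes differed here than against sham, 509 higher and 479 lower by edgeR, 155 and 194 by 2-fold or more. Values at 3 h and 6 h did not overlap for 34.6% of genes, against 10% by chance. The counts were 1068 and 1043 without sham replicate 1, 191 and 209 without 3 h replicate 1, 264 and 286 without 3 h replicate 3, 212 and 189 without 6 h replicate 2 and 247 and 205 without 6 h replicate 3, and the higher count was 315 without 3 h replicate 2. The share of calls that were higher, 51.5% here, was 33.0% with TPM and 29.9% with library totals, which moved the median of all genes by -0.12.

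The comparison of 12 h with 6 h asks what is switched off and on as growth approaches. Immediate early genes fell back: 21 of 33 tested genes fell, or 25 adjusted over the list alone. A median log2 difference of -1.30 was found (camera adjusted p = 5.78e-10, adjusted p = 0.221 with an estimated correlation). Examples were Egr1 (-3.82), Btg2 (-3.51), Gadd45g (-2.92) and Dusp5 (-2.92). IL-6 and STAT3 targets fell with them: 11 of 14 tested genes fell, or 11 adjusted over the list alone. At list level the median log2 difference was -0.92 (camera adjusted p = 1.41e-05, adjusted p = 0.144 with an estimated correlation). Socs3 went from 46.8 ± 10.6 to 15.7 ± 1.26 FPKM (-1.55 ± 0.35, edgeR adjusted p = 0.00636). Acute phase transcripts came down from their 6 h levels: 1 of 29 tested genes rose and 16 fell, or 1 and 19 adjusted over the list alone. Taking all tested members, the median log2 difference was -0.62 (camera adjusted p = 3.56e-06, adjusted p = 0.187 with an estimated correlation). Mt1 fell by 2.54 ± 0.39. In DNA replication, favoured by the filter, 22 of 23 tested genes rose, or 22 adjusted over the list alone. Their median log2 difference was 2.01 (camera adjusted p = 1.57e-18, adjusted p = 0.144 with an estimated correlation). Among them were Uhrf1 (5.64), Mcm5 (4.45) and Mcm2 (3.95). G1 to S cyclins and regulators rose as well: 12 of 16 tested genes rose and 1 fell, or 13 and 1 adjusted over the list alone. The list had a median log2 difference of 1.40 (camera adjusted p = 7.36e-07, adjusted p = 0.0196 with an estimated correlation). The G1 to S gene that fell was Cdkn1a (-6.17 ± 0.34, edgeR adjusted p = 9.69e-07). Cholesterol synthesis genes were higher: 18 of 25 tested genes rose and 1 fell, or 19 and 2 adjusted over the list alone. This gave a median log2 difference of 1.21 (camera adjusted p = 7.63e-09, adjusted p = 0.248 with an estimated correlation). These included Hmgcs1 (2.44), Fdps (2.36) and Fdft1 (2.01). Cyp7a1 rose from 0.237 ± 0.124 to 29.8 ± 16.1 FPKM (6.97 ± 0.75, edgeR adjusted p = 3.96e-05). Igfbp1 fell from 765 ± 70.4 to 17.7 ± 9.16 (-5.42 ± 0.33, edgeR adjusted p = 1.4e-06). Ccnd1 rose by 1.57 ± 0.30 and Alb fell by 0.68 ± 0.13. Fos (-2.06, edgeR adjusted p = 0.0503), Jun (-1.30, edgeR adjusted p = 0.0575), Hgf (0.78, edgeR adjusted p = 0.0624), Myc (0.41), Atf3 (-0.72) and Saa1 (-0.13) did not pass. Fos did pass at -2.05 without sham replicate 1, at -2.06 without any single 3 h library and at -2.96 without 12 h replicate 1. Jun passed at -1.30 without sham replicate 1 or 2, and Hgf at 0.78 without sham replicate 1 or 3 and 0.98 without 6 h replicate 3. Alb lost its call after quantile normalization (-0.36).

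The circadian clock list turned over between 6 h and 12 h: 11 of 19 tested genes rose and 4 fell, or 11 and 5 adjusted over the list alone. The median log2 difference was 1.24 (camera adjusted p = 0.00389, adjusted p = 0.144 with an estimated correlation). That call was lost with TPM (median 1.46) and library totals (1.54). Dbp rose from 0.251 ± 0.122 to 15.3 ± 1.70 FPKM (5.92 ± 0.54, edgeR adjusted p = 1.04e-05), with the clock repressor Per3 (5.60 ± 0.39) and the clock-controlled kinase Wee1 (4.80 ± 0.36). The clock activator Npas2 fell, with 7 counts at 12 h against 453 at 6 h, 81.0-fold lower (counting interval 39.0 to 203). Genes of liver-specific functions were lower: in the urea cycle and amino acid breakdown, 16 of 26 tested genes fell, or 19 adjusted over the list alone. As a list, the median log2 difference was -0.61 (camera adjusted p = 1.97e-08, adjusted p = 0.187 with an estimated correlation). Members included Sds (-2.43) and Tat (-1.62). Among secreted liver proteins, 16 of 29 tested genes fell, or 16 adjusted over the list alone. Over the whole list the median log2 difference was -0.44 (camera adjusted p = 0.000243, adjusted p = 0.206 with an estimated correlation). The thyroid hormone carrier transthyretin, Ttr, was lower (-0.92). In gluconeogenesis and glucose output, 2 of 19 tested genes rose and 9 fell, or 2 and 10 adjusted over the list alone. Across tested members the median log2 difference was -0.61 (camera adjusted p = 0.0137, adjusted p = 0.221 with an estimated correlation). These calls for secreted proteins and glucose output were lost after quantile normalization, with medians of -0.04 and -0.37. The secreted lysyl oxidase Loxl4 fell by 4.59 ± 0.90, from 6.50 ± 3.64 to 0.263 ± 0.186 FPKM. Mup10, a close copy of other Mup genes, owed its difference of 7.68 (edgeR adjusted p = 0.0423) to 12 h replicate 3, which held 1049 FPKM against 2.68 and 2.72. It was not called at 0.67 without 12 h replicate 3 or at 7.68 without sham replicate 2, and 7.74, 7.53 and 7.78 without 6 h replicates 1, 2 and 3.

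Camera called 11 further lists lower at 12 h than at 6 h, given as median log2 differences. Of cell type lists these were endothelial cells (-0.44), monocytes and macrophages (-0.61) and the 3 tested genes of neighbouring tissue (-1.62), with adjusted p = 0.452, 0.288 and 0.206 with an estimated correlation. The monocyte call was lost at -0.61 without sham replicate 1, -0.40 without 6 h replicate 3 and -0.56 without 12 h replicate 3 and the neighbouring tissue call at -1.63 without 12 h replicate 3. Without a filter both calls were lost (-0.35 and -0.73), that for monocytes also without both doubted libraries (-0.40), and that for neighbouring tissue also with voom (-1.63) and limma on FPKM (-0.87). In protein synthesis they were ribosome biogenesis (-0.34, but 0.016 with TPM), cytosolic ribosomal proteins (-0.21, but 0.13 with TPM, 0.09 with library totals and 0.039 after quantile normalization) and translation factors (-0.22, but 0.11 with TPM and 0.08 with library totals). These had adjusted p = 0.33, 0.724 and 0.383 with an estimated correlation. The ribosomal protein call was lost at -0.21 and -0.17 without 12 h replicates 1 and 3 and the median was -0.32 without 12 h replicate 2. The translation factor call was lost at -0.16 without 12 h replicate 1. In metabolism they were the respiratory chain (-0.38), metallothioneins and metal handling (-0.55), periportal genes (-0.35), lipid droplets (-0.69) and P450 enzymes (-0.35, but 0.00054 with TPM). These had adjusted p = 0.616, 0.144, 0.327, 0.424 and 0.411 with an estimated correlation. The lipid droplet call was lost at -0.23 without 6 h replicate 1 and -0.41 without 12 h replicate 3 and the P450 call at -0.32 without 12 h replicate 3. Quantile normalization ended the calls for monocytes, neighbouring tissue, ribosomal proteins, translation factors, the respiratory chain, periportal genes, lipid droplets and P450 enzymes.

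**Figure D4:**
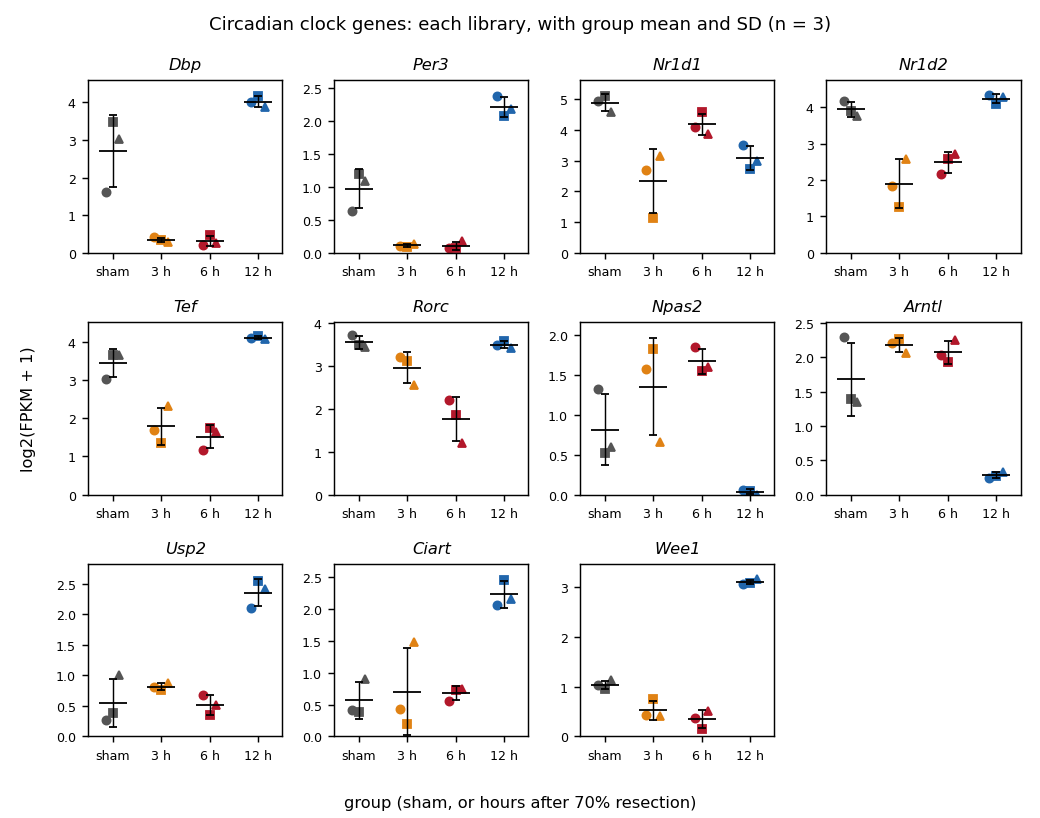
Expression as log2(FPKM + 1) of the clock genes with the largest differences, by group (sham, and 3, 6 and 12 h after 70% resection), with each library as a symbol for its replicate and the bar as group mean ± SD (n = 3). Dbp averaged 6.46 FPKM in sham, 0.276 at 3 h, 0.251 at 6 h and 15.3 at 12 h, and Npas2 0.815, 1.70, 2.19 and 0.0265.

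By edgeR 1387 genes were higher and 1441 lower at 12 h than at 6 h, 705 and 516 of them by 2-fold or more. Values at 6 h and 12 h did not overlap for 46.8% of genes, against 10% by chance. From 3 h to 12 h 2041 were higher and 2085 lower, 808 and 929 by 2-fold or more, with no overlap for 55.2%. The count lower at 12 h than at 6 h was 2229 without sham replicate 1, 906 without 6 h replicate 2, 950 without 12 h replicate 2 and 937 without 12 h replicate 3. The share of calls that were higher moved from 49.1% to 86.5% with TPM and 84.8% with library totals between 6 h and 12 h, where library totals moved the median of all genes by 0.26. Between 3 h and 12 h it moved from 49.5% to 74.0% and 69.7%, and library totals moved the median by 0.17.

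The early changes were largely shared between 3 h and 6 h. Of the genes called against sham, 932 were higher at both times and 1052 lower at both, where independent calls would give 188.7 and 244.3, and 7 were called in opposite directions. Between 3 h and 12 h 496 were higher and 479 lower at both (151.7 and 205.7 if independent) and 131 were opposite, among them Dbp, Igfbp1 and the lipogenic regulator Thrsp. Between 6 h and 12 h 935 were higher and 969 lower at both (259.9 and 318.1 if independent), 86 were opposite, and the count higher at both was 1515 without sham replicate 1. The log2 differences correlated across genes, which are not independent replicates, at 0.82 for 3 h and 6 h, 0.45 for 3 h and 12 h and 0.62 for 6 h and 12 h. Their covariances were 0.757, 0.348 and 0.581. Unchanged groups simulated against the same sham libraries gave 0.0105, 0.0114 and 0.0111 and 0 shared calls. With almost no calls (means of 0 to 0.05 in 20 draws) they set no baseline. The part of shared controls stays open, since 3 sham libraries cannot be divided.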

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

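The clock test of sham replicate 1, the tests of the clock gene and Lcn2 explanations, and the list tests between 12 h and 3 h, were chosen only after the results were seen, while the other tests of sham replicate 1 were set down earlier. The changes from sham at 12 h differed from those at 3 h, tested directly by edgeR between the 2 times, for 10 of 14 fixed genes. Lower at 12 h than at 3 h were Fos (-2.80), Jun (-1.58), Socs3 (-1.06), Cdkn1a (-6.33), Igfbp1 (-4.84), Mt1 (-1.675) and Alb (-0.78). Higher were Ccnd1 (1.96), Cyp7a1 (4.14) and Mcm5 (3.66).

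The same held by camera for 25 of 43 lists, 5 higher and 20 lower at 12 h than at 3 h, given here as median log2 differences. With an estimated correlation only the G1 to S list was called (adjusted p = 0.0203 with an estimated correlation), and the other 24 had adjusted p = 0.173 to 0.742 with an estimated correlation. Higher were G1 to S regulators (1.645), DNA replication (1.94), cholesterol synthesis (1.03), the clock (0.77) and the unfolded protein response (0.62). Of signalling and stress lists, lower were immediate early genes (-1.65), IL-6 and STAT3 targets (-1.03), interferon-stimulated genes (-0.65), NRF2 targets (-0.50) and cytosolic ribosomal proteins (-0.31, but 0.07 after quantile normalization). Of metabolic lists, lower were fatty acid synthesis (-1.25), amino acid breakdown (-0.84), lipid droplets (-0.74), metallothioneins and metal handling (-0.70), P450 enzymes (-0.68), glucose output (-0.67), the respiratory chain (-0.53), secreted proteins (-0.45), bile acids (-0.44) and periportal genes (-0.34). Of cell type lists, lower were 3 neighbouring tissue genes (-1.76), red blood cells (-1.70), stellate cells (-0.90), endothelial cells (-0.85) and Kupffer cells (-0.44). The call for NRF2 targets was lost without each of 6 libraries, with medians of -0.50 and -0.50 without sham replicates 1 and 3, -0.30 and -0.60 without 3 h replicates 1 and 3, and -0.55 and -0.46 without 12 h replicates 1 and 3, and that for ribosomal proteins without each of 4, with -0.25 and -0.19 without 3 h replicates 1 and 3, and -0.27 and -0.23 without 12 h replicates 1 and 3. Quantile normalization ended the calls for NRF2 targets (-0.17), bile acids (-0.14), glucose output (-0.29), P450 enzymes (-0.28), secreted proteins (-0.22), periportal genes (-0.01) and the respiratory chain (-0.20). Medians moved for the clock to 1.19 without 3 h replicate 3, for interferon-stimulated genes to -0.99 without 12 h replicate 2 and for periportal genes to -0.22 without 3 h replicate 3.

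For why sham replicate 1 stood apart, 3 explanations were tested. More mitochondrial reads alone are argued against, since 1224 nuclear genes scaled without them still lay over 2-fold from both other shams, against 281 in the highest other library. RNA of another cell type is argued against, since no such list reached the sign set, a median of 1. Neighbouring tissue (0.82) stays open, with 3 of 19 markers tested. Another clock time or phase may contribute: the median absolute difference of the clock list, 0.71 against 0.48 for all genes, was at the 96.4th percentile of 10000 random lists matched on expression. The clock was not particular in this, since 9 of 43 lists had a larger median absolute difference, among them immediate early (1.45), mitochondrially encoded (0.99) and lipid droplet genes (0.94), seen afterwards and not tested.

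Clock genes differed between the groups, in opposite directions at 3 h and 12 h for Dbp and Per3. An effect of sham replicate 1 alone is argued against, because between 12 h and 6 h, a contrast without sham libraries, 15 of 19 clock genes (78.9%) were called, against 24.7% of all genes. Harvest at other times of day could produce such a pattern as well as resection, and the tests cannot tell these apart, since the labels give no clock times. Between 6 h and 3 h 2 clock genes were called.

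Lcn2 is in the acute phase and the neutrophil list (6 of 18 genes tested), and its rise could come from liver or neutrophils. Neutrophils as the main source are argued against, since S100a8 and S100a9 together rose by 8.53 FPKM at 6 h, 0.894% of the 954.7 FPKM rise of Lcn2. More blood in the resected livers is argued against as the whole cause at 6 h, since S100a8 and S100a9 rose by 3.16 ± 0.55 (SE) more on the log2 scale than the 4 haemoglobin genes (2.95 against -0.21). At 3 h, compared after the values were seen, the haemoglobin genes were higher as well (0.89 against 3.00 for S100a8 and S100a9, a gap of 2.11 ± 0.55), so a part from blood stays open there. Which liver cells made the Lcn2 mRNA was not analysed here.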

How the results depend on the processing

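The alternatives added after the data were seen (limma on FPKM, DESeq2, library totals, scaling without mitochondrial and acute phase genes, both doubted libraries left out) were chosen only then, and the others were planned. Depth limits the text to genes with 1 FPKM or more, the 3 libraries per group limit the smallest change found, and TPM or library totals shifted the balance of higher and lower calls. The cause was not tested for any value below. Counts not given stayed within 1.5 times the reported count.

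Counts are given as higher and lower. With TPM they were 727 and 2370 at 3 h, 1028 and 3653 at 6 h, 293 higher between 3 h and 6 h, 3372 and 528 between 6 h and 12 h, 3374 and 1186 between 3 h and 12 h, 539 and 2027 shared by 3 h and 6 h, and 725 lower shared by 3 h and 12 h. With library totals (added) they were 2346 lower at 3 h, 1048 and 3706 at 6 h, 325 and 761 between 3 h and 6 h, 3122 and 561 between 6 h and 12 h, 3114 and 1356 between 3 h and 12 h, and 586 and 2004 shared by 3 h and 6 h. With a 2-fold minimum they were 577 and 602 at 3 h, 826 and 1031 at 6 h, 556 and 746 at 12 h, 155 and 194 between 3 h and 6 h, 705 and 516 between 6 h and 12 h, 808 and 929 between 3 h and 12 h, and shared 457 and 459 (3 h and 6 h), 209 and 167 (3 h and 12 h) and 314 and 362 (6 h and 12 h). With only the 6 libraries compared they were 768 lower at 3 h, 1011 higher at 12 h, 776 lower between 3 h and 6 h, and shared 662 lower (3 h and 6 h), 308 and 265 (3 h and 12 h) and 565 higher (6 h and 12 h). Without both doubted libraries (added) they were 2723 and 2771 at 12 h, 2178 lower between 6 h and 12 h, and 754 and 726 shared by 3 h and 12 h, and with DESeq2 (added) 828 lower between 3 h and 6 h. With an estimated correlation 1, 1 and 2 lists were called at 3, 6 and 12 h against sham, and 0, 1 and 1 by camera between 3 h and 6 h (unadjusted p under 0.05 for 6 lists, fry calling 12), 6 h and 12 h, and 3 h and 12 h. Without a filter 26 lists were called at 6 h, and with quantile normalization 13 between 6 h and 12 h. Reversed were secreted proteins at 3 h with quantile normalization (-0.16), ribosomal proteins between 6 h and 12 h (0.039) and 3 h and 12 h (0.066) with quantile normalization, and Alb at 6 h with TPM (-0.30), by the direction of the test. Medians of called lists also changed sign with TPM and library totals for secreted proteins at 3 h (-0.05 and -0.023), ribosomal proteins (-0.08 and -0.10) and metallothioneins (-0.16 and -0.17) at 6 h, and ribosomal proteins (0.13 and 0.09) and translation factors (0.11 and 0.08) between 6 h and 12 h. With TPM they did so too for the respiratory chain at 3 h (-0.0032), and ribosome biogenesis (0.016) and P450 enzymes (0.00054) between 6 h and 12 h. Calls were also lost for Jun at 3 h with library totals (1.31) and only 6 libraries (1.54), Hgf at 3 h with limma (0.49), DNA replication at 6 h with limma (-0.15) and without both doubted libraries (-0.39), the clock at 6 h with TPM (-1.05), Myc at 6 h with only 6 libraries (1.23), Cyp7a1 between 3 h and 6 h after quantile normalization (-1.09) and with limma (-1.08), and Mup8 there with voom (4.26) and limma (3.82).

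Without 1 library at a time the counts were 826 to 1274 higher and 884 to 1398 lower at 3 h, 1585 to 2437 higher and 1709 to 2463 lower at 6 h, 981 to 2597 higher and 1131 to 2666 lower at 12 h, 191 to 1068 higher and 189 to 1043 lower between 3 h and 6 h, 947 to 1971 higher and 906 to 2229 lower between 6 h and 12 h and 1396 to 2734 higher and 1424 to 2799 lower between 3 h and 12 h. Genes differing across groups were 4710 to 7430. Shared calls, higher and lower, were 717 to 1092 and 763 to 1179, 366 to 689 and 338 to 664 and 639 to 1515 and 723 to 1425. Lists called were 16 to 23, 13 to 20 and 12 to 17 against sham, 12 to 17 between 3 h and 6 h, 17 to 26 between 6 h and 12 h and 23 to 25 between 3 h and 12 h. Without sham replicate 1, 16 of 114 list calls were lost. With the replicate number as a block, 1013 and 1182 genes were called at 3 h, 1799 and 1947 at 6 h, 1400 and 1574 at 12 h, and 1 of 114 list calls (amino acid breakdown at 12 h) and 2 named gene calls (Hgf at 3 h, Mup10 between 6 h and 12 h) were lost and 1 (Fos between 6 h and 12 h) was gained, with no other list or named gene call changed. The numbers do not pair the libraries: same-numbered libraries deviated with correlations of -0.255 to 0.173, and 1 of 12 correlated best with its own number.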

Other observations

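The genes of this part belong to lists that camera did not call against sham, or are said to have been picked later, and its tests were set before the results were seen except the choice of 3 genes named below and the list splits between 3 h and 12 h. Growth factors and receptors of liver regeneration were not called at 3 h (camera adjusted p = 0.104), and 8 of 19 tested genes rose and 3 fell, or 8 and 3 adjusted over the list alone. Inhbb, the activin B subunit, rose at 3, 6 and 12 h (3.16, 3.23 and 2.37), Plaur, the urokinase receptor, at 3 h and 6 h (2.62 and 2.42), and the endothelial ligand Wnt2 at 3 h (1.28). Among NRF2 oxidative stress targets, not called at 6 h (camera adjusted p = 0.73), 4 of 16 tested genes rose and 4 fell, or 4 and 4 adjusted over the list alone. The heme oxygenase Hmox1 was higher at 3 h and 6 h (2.90 and 2.10), and the growth inhibitor Osgin1 lower at 3, 6 and 12 h (-2.19, -3.35 and -2.15).

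Hepatocyte transcription factors were not called at 6 h (camera adjusted p = 0.396), and 1 of 18 tested genes rose and 6 fell, or 2 and 6 adjusted over the list alone. Cebpa, which restrains hepatocyte growth, was lower at 3 h and 6 h (-1.24 and -1.21), the xenobiotic receptor Nr1i3 lower at 6 h (-1.61) and Hnf4a, a regulator of hepatocyte identity, higher at 3 h (1.07). Of the genes called in opposite directions at 3 h and 12 h, 3 were chosen after their values were seen. The replication licensing inhibitor Gmnn went from -1.42 at 3 h to 1.73 at 12 h, while the sterol sensor Insig2 (1.87 and -1.10) and the mitochondrial unfoldase subunit Clpx (0.91 and -1.86) went the other way.

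The groups were compared with other splits. For genes differing across the 4 groups, chance can be excluded: 1 of 100 splits, the real one, called as many, 5725 against 371 in the highest other. For 2 groups 10 splits are too few for a share under 0.05, and the others keep part of the difference. The real split called most genes (1 of 10 in each), with 2468 and a highest other of 0 by edgeR at 3 h against sham, 4004 and 0 at 6 h, 3298 and 0 at 12 h, 988 and 0 between 3 h and 6 h, 2828 and 1 between 6 h and 12 h, and 4126 and 0 between 3 h and 12 h. For lists, 2 of 10 splits called as many as the real one at 3 h (20, highest other 21), 3 at 6 h (17, highest other 20), 3 at 12 h (16, highest other 17), 2 between 3 h and 6 h (15, highest other 15), 1 between 6 h and 12 h (21, highest other 19) and 1 between 3 h and 12 h (25, highest other 23).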
